A study of Caenorhabditis elegans with 54 samples.

How the data were processed

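RNA was sequenced from day 1 adult C. elegans grown at 20 °C, per the labels, in 9 experiments of 6 libraries each: 3 of a ribosome-bound fraction and 3 of total RNA. For the gradients the labels give about 12000 worms per replicate, 1 mM cycloheximide and 15 to 60% sucrose. How the IP was washed and how libraries were made is not in the labels. The series description gives strain WBM1471 for both the neurons B and the intestine experiments, while the sample labels give WBM1470 for the intestine, and the sample labels were followed.

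Per the submitters' processing notes, kallisto 0.46.1, DESeq2 1.30.1, R 4.0.4 and genome build ce11 were used, with no role or order stated. The per-library values deposited by the authors are normalized counts (unit: signal), which are not whole numbers and were normalized separately in each of the 9 tables. The authors' columns log2FoldChange and lfcSE are the log2 ratio of fraction over total RNA and its standard error (unit: log2). The authors' stat column is the Wald statistic (unit: score). The authors' pvalue and padj columns are p-values (unit: p_value), and their neglog10_padj column is -log10 of the adjusted p (unit: neg_log10_p). Whole read counts could not be recovered from these values. The tables list 20728 distinct gene identifiers, of which 19405 have a symbol in the Ensembl release 115 annotation of WBcel235, which gave symbols and positions.

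Depth was estimated from the size of a single count in each library, between 0.350 and 7.14 normalized counts. It gave 7.04 to 78.8 (median 33.1) in units of 1e6 reads per library, and from 83 to 7896 listed genes stood at 0. Correlations between replicates of a group, across genes, ran down to 0.644 in the neurons A IP and to 0.818 in the intestine IP.

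Each fraction was compared with its own total RNA by limma-trend (limma 3.58.1, R 4.3.3) on log2 of the normalized count plus 1, over genes with a mean of at least 10, with Benjamini-Hochberg adjusted p under 0.05. A difference between 2 experiments was the interaction term over their 12 libraries. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. All tests are two-sided. The main test, the gene lists, the rule for named genes and all alternatives but those named below as added later were chosen before the data were examined.

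The named genes were rpl-22 and the 4 promoter genes, then the 8 largest changes in each direction. These had to pass the threshold, to lie in the upper part of the abundance range, to carry a gene symbol and to have every fraction library on one side of every total library. For a difference that last condition was applied in at least 1 of the 2 experiments. To these came the 4 most abundant tested members of each list described. Chance puts 10% of genes with 3 libraries against 3 on separate sides.

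Of 27 gene lists tested, those described were intestine (33 genes), body wall muscle (35), pharynx (21), pan-neuronal (35), neurotransmitter (18), neuropeptide (70), ciliated sensory neuron (43), epidermis and cuticle (39), germline and oocyte (50), major sperm protein (31), GLD-1 target (17), mitochondrially encoded (12), cytosolic ribosomal protein (83), mitochondrial ribosomal protein (70), nuclear-encoded oxidative phosphorylation (32), proteasome (31), vacuolar ATPase (21), histone (77), collagen (150), translation factor (41), C-type lectin and lysozyme with saposin-like genes (246) and chemoreceptor (866). Of the 17 GLD-1 targets, 12 also stand on the germline list. Lists were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation.

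Whether replicate numbers pair a fraction with its total RNA was checked by correlating their deviations from the group means across genes. The lowest correlation was above 0.1 in the intestine (0.304), neurons A (0.313) and ubiquitous (0.187) experiments and at or below it in the other 6. In neurons A the libraries did not all correlate best with their own number, and a replicate block was run as an alternative. Further alternatives were pseudocounts of 0.5 and 5, no filter on low values, leaving out each replicate, camera's estimated correlation and limma's fry test, and Spearman correlation. Scaling each library to an equal sum, the authors' deposited test and leaving out single libraries were added after the data had been seen. Equal-sum scaling moved the median log2 of all genes by -1.15 in intestine, -1.37 in muscle, -0.43 in neurons A, -0.40 in neurons B, 0.24 in ubiquitous, -0.26 in ubiquitous polysomes and -0.37 in wild-type polysomes, and by under 0.1 in the other 2.

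With 200 simulated changed genes the test recovered from 0% (neurons A) and 10% (intestine) to 88.3% (pooled fractions) of 4-fold changes. Unchanged genes made 0% to 7.39% of its calls in single comparisons. They reached 26.5% in neurons A against ubiquitous IP and 20.4% in neurons A against B. Most comparisons called more genes, a case not simulated.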

Results

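The data are RNA sequencing of Caenorhabditis elegans as 54 libraries in 18 groups of 3 replicates. Animals were day 1 adults grown at 20 °C, per the labels. In 6 experiments RNA was taken from ribosomes immunoprecipitated (IP) through a tagged copy of the ribosomal protein RPL-22, and total RNA of the same strain was sequenced beside it. The tag was expressed from the nep-17 promoter in the intestine strain, from the myo-3 promoter in the muscle strain, from the rab-3 promoter in the strains here called neurons A (MSD473) and neurons B (WBM1471), and from the eft-3 promoter in the soma strain. In the ubiquitous strain (MSD470) the endogenous rpl-22 gene carried the tag. In 3 further experiments ribosomes were separated on a sucrose gradient: polysomes of wild-type animals (Bristol N2), polysomes of the ubiquitous strain, and pooled 60S, 80S and polysome fractions of the ubiquitous strain. The tables held normalized read counts with a median sum per library, in units of 1e6, of 34.8 and a highest of 85.8 (muscle IP replicate 2), while intestine total RNA replicate 1 held the lowest. The read numbers estimated from the size of a single count ran, in the same unit, from 7.04 (intestine IP replicate 2) to 78.8 (muscle total RNA replicate 3). Values below are normalized counts as mean ± SD with n = 3 libraries per group, and log2 ratios are of the fraction over total RNA with their standard error (SE). The p-values measure the spread between these libraries, since the labels do not say whether replicates were separate cultures.

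The tagged gene rpl-22 (WBGene00004434, chromosome II, 5055616 to 5056214, build WBcel235) has 1 entry in the tables, which does not tell tagged from endogenous copies. In the intestine experiment it stood at 55100 ± 3550 in the IP and 30830 ± 7447 in total RNA (log2 0.86, SE 0.32, adjusted p = 0.0783). It rose in the muscle IP, with 293000 ± 60110 against 59940 ± 29090 (log2 2.37, SE 0.31, adjusted p = 0.000105). It also rose in the neurons B IP, with 134300 ± 64880 against 36100 ± 17280 (log2 1.90, SE 0.52, adjusted p = 0.00786). The neurons A values were 57060 ± 8532 in the IP and 53300 ± 20840 in total RNA (log2 0.15, SE 0.55, adjusted p = 0.843). The soma values were 155400 ± 43160 and 105500 ± 22400 (log2 0.55, SE 0.26, adjusted p = 0.0915). The ubiquitous IP held 239100 ± 13710 against 135600 ± 67850 (log2 0.93, SE 0.34, adjusted p = 0.0575). In polysomes rpl-22 rose in all 3 experiments, from 44650 ± 8472 to 130100 ± 58480 in the ubiquitous strain (log2 1.47, adjusted p = 0.00447), from 49920 ± 2369 to 93380 ± 21450 in the pooled fractions (log2 0.88, adjusted p = 0.00276) and from 31580 ± 2119 to 81550 ± 15000 in wild type (log2 1.35, adjusted p = 3.65e-06). With every library scaled to an equal sum the intestine and neurons A ratios of rpl-22 turned to -0.33 and -0.32, and the other ratios kept their sign.

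The intestine comparison asked which transcripts were on ribosomes of intestinal cells. nep-17 (WBGene00010070, chromosome II, 13507819 to 13516478), the peptidase gene whose promoter drove the tag, rose from 2088 ± 628 in total RNA to 20950 ± 6406 in the IP (log2 3.32, SE 0.35, adjusted p = 0.000412, n = 3 per group). The carbonic anhydrase gene cah-4 (WBGene00000282, chromosome X, 13542574 to 13544599) rose from 1930 ± 581 to 504000 ± 280600 (log2 7.84, SE 0.55, adjusted p = 0.000139). The yolk protein genes vit-5 (log2 3.79, SE 0.56), vit-2 (log2 3.59, SE 0.59) and vit-3 (log2 4.44, SE 0.93) rose together, and vit-2 reached 1426000 ± 278300 against 136900 ± 95790. Of the intestine list, 31 of 33 rose (32 adjusted over the list alone) (median 3.79, camera adjusted p = 9.69e-19, adjusted p = 0.0198 with an estimated correlation), with dct-16 at log2 5.52. Among C-type lectin, lysozyme and saposin-like genes, which encode secreted defence proteins, 92 of 152 rose and 5 fell (95 and 8 over the list alone) (median 3.72, camera adjusted p = 8.25e-17, adjusted p = 0.171 with an estimated correlation). Examples were the saposin-like genes spp-5 (log2 5.05, SE 0.48) and spp-14 (log2 5.10, SE 0.75), the lysozyme gene ilys-5 (log2 4.99, SE 0.68) and the lectin gene clec-63 (3.54). Further large rises were cpf-1 (6.08), a cleavage and polyadenylation factor gene, the lysozyme gene lys-10 (5.90), chil-21 (5.90), the haem transport gene hrg-3 (5.87), sysm-1 (5.72) and spp-23 (5.71). pud-1.1 was also past the threshold (log2 9.66, adjusted p = 0.0272), but its near-identical copy pud-1.2 makes its counts uncertain. Of vacuolar proton pump genes 7 of 21 rose and 2 fell (13 and 3 over the list alone) (median 1.50, camera adjusted p = 0.0026, adjusted p = 0.813 with an estimated correlation), including the intestinal subunit gene vha-6 (log2 3.74, SE 0.34).

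Several genes of lists named for other cells rose in the intestine IP. These included cat-4 (4.41) and bas-1 (3.20) of the neurotransmitter list, which make biogenic amines, and nlp-40 (3.69) and nlp-36 (4.03) of the neuropeptide list. The syntaxin gene unc-64 (3.19) of the pan-neuronal list rose too, as it did in all 5 promoter-driven IPs. Of nuclear-encoded oxidative phosphorylation genes 18 of 32 rose and 1 fell (19 and 1 over the list alone), including cox-4 (1.89) and atp-5 (1.39) (median 1.10, camera adjusted p = 9.27e-05, adjusted p = 0.608 with an estimated correlation), though with equal-sum scaling the median of this list turned to -0.09. Germline transcripts fell: 42 of 50 fell (45 over the list alone) in the germline and oocyte list (median -1.58, camera adjusted p = 9.03e-14, adjusted p = 0.378 with an estimated correlation), among them the eggshell proteoglycan genes cpg-1 (log2 -1.77, SE 0.25) and cpg-2 (-1.37) and the eggshell gene cbd-1 (-1.92). Of the germline mRNAs that the repressor GLD-1 binds, 15 of 17 fell (17 over the list alone), including puf-5 (-1.75) and spn-4 (-1.62). Large falls included lin-7 (log2 -3.35, SE 0.99), the geminin gene gmn-1 (-2.85), the germ granule gene meg-4 (-2.44) and puf-6 (-2.41). Of body wall muscle genes 10 of 33 fell (10 over the list alone), with the troponin C gene pat-10 (-1.79) and the actin gene act-4 (-1.16), while myo-3 gave log2 -2.02 without passing (adjusted p = 0.0709). Of mitochondrially encoded mRNAs 4 of 12 fell (8 over the list alone). The GLD-1, muscle and mitochondrial lists had camera adjusted p from 5.46e-07 to 0.00148, and adjusted p from 0.564 to 0.608 with an estimated correlation. limma called 2427 genes risen and 1310 fallen of 13629 tested, and with replicates as a block 3122 and 2891. With equal-sum scaling 1509 rose and 5484 fell (21.6% risen against 65.0%). Without replicate 1 the total was 1029, and intestine IP replicate 2 stood apart with 6112 genes at 0 (34.4%).

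The muscle comparison asked the same of body wall muscle. myo-3 (WBGene00003515, chromosome V, 12226817 to 12234343), the muscle myosin heavy chain gene whose promoter drove the tag, rose from 2293 ± 359 to 24410 ± 3440 (log2 3.41, SE 0.21, adjusted p = 1.81e-07, n = 3 per group). The troponin C gene pat-10 rose from 52520 ± 31010 to 3880000 ± 999600 (log2 6.32, SE 0.36, adjusted p = 1.14e-07). Of the body wall muscle list 35 of 35 rose (35 over the list alone) (median 4.84, camera adjusted p = 1.31e-27, adjusted p = 0.564 with an estimated correlation), with the actin gene act-4 (log2 5.10, SE 0.20) and the myosin light chain genes mlc-2 (log2 5.51, SE 0.20) and mlc-1 (log2 5.86, SE 0.26). Other large rises were cpg-9 (6.91), txt-14 (6.79), the transthyretin-like gene ttr-16 (6.71), the calcium sensor gene ncs-4 (6.69), the profilin gene pfn-3 (6.63), oig-2 (6.63), the insulin-like gene ins-27 (6.62) and heh-1 (6.53). Nuclear-encoded oxidative phosphorylation genes rose: 28 of 32 rose and 2 fell (28 and 2 over the list alone) (median 2.52, camera adjusted p = 3.24e-12, adjusted p = 0.564 with an estimated correlation), with the ATP synthase genes atp-2 (2.20), atp-1 (2.17), atp-5 (2.99) and atp-3 (2.79). Of mitochondrial ribosomal protein genes 38 of 70 rose (42 over the list alone) (median 0.69, camera adjusted p = 4.56e-06, adjusted p = 0.637 with an estimated correlation), but their median turned to -0.70 with equal-sum scaling.

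Lists named for other cells held members that rose in the muscle IP. On the germline list these were perm-2 (4.84) and perm-4 (3.82), vitelline layer genes. On the neuronal lists they were the ankyrin gene unc-44 (5.03), the G protein gene egl-30 (3.18), the GABA transporter gene snf-11 (5.11) and the cyclic nucleotide channel gene tax-2 (4.21). On the lectin and lysozyme list they were the saposin-like genes spp-10 (5.43) and spp-15 (6.31). Intestinal genes fell: 1 of 32 rose and 24 fell (1 and 24 over the list alone) (median -0.80, camera adjusted p = 3.44e-06, adjusted p = 0.594 with an estimated correlation), with vit-2 (-0.76), vit-5 (-0.79) and the aspartyl protease gene asp-1 (-0.99), and nep-17 fell to log2 -1.38. Of collagens 2 of 107 rose and 60 fell (3 and 65 over the list alone), with col-119 (-1.32), and of lectin and lysozyme genes 7 of 130 rose and 52 fell (7 and 58 over the list alone), with ilys-5 (-0.96). Of germline and oocyte genes 2 of 50 rose and 27 fell (2 and 31 over the list alone), with cpg-1 (-0.93). Of major sperm protein genes, whose copies are nearly alike, 25 of 28 fell (27 over the list alone). The collagen, lectin, germline and sperm protein lists had camera adjusted p from 2.13e-09 to 3.44e-06, and adjusted p from 0.564 to 0.594 with an estimated correlation. Large falls included the bestrophin gene best-18 (log2 -2.35, SE 0.53), col-73 (-2.09), dod-19 (-1.84) and the collagen gene dpy-4 (-1.79). limma called 3388 genes risen and 1923 fallen of 14681. Equal-sum scaling left 1689 risen and 10452 fallen (13.9% risen against 63.8%). The total was 8751 without replicate 1, 2985 without replicate 2 and 2725 without replicate 3.

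Both neuronal strains asked which transcripts were on ribosomes of neurons. In neurons A, rab-3 (WBGene00004267, chromosome II, 5721767 to 5727853), the synaptic vesicle GTPase gene whose promoter drove the tag, rose from 117 ± 37.8 to 11670 ± 10300 (log2 6.06, SE 0.93, adjusted p = 0.00527, n = 3 per group). The neuropeptide processing genes sbt-1, at 133900 ± 51820 against 866 ± 196 (log2 7.21, SE 0.53, adjusted p = 0.000705), and egl-3 (log2 7.01, SE 0.49) rose, as did the complexin gene cpx-1 (log2 9.30, SE 1.21) and the synaptotagmin gene snt-1 (log2 8.25, SE 1.19). Of neuropeptide genes 66 of 69 rose (66 over the list alone) (median 6.75, camera adjusted p = 7.34e-34, adjusted p = 0.253 with an estimated correlation), including flp-18 (8.70), nlp-9 (8.58), nlp-12 (8.03) and flp-14 (7.94). Of pan-neuronal genes 23 of 35 rose (25 over the list alone) (median 5.38, camera adjusted p = 2.47e-13, adjusted p = 0.157 with an estimated correlation). Of neurotransmitter genes 11 of 18 rose (11 over the list alone) (median 5.68, camera adjusted p = 1.06e-06, adjusted p = 0.449 with an estimated correlation), including the GABA synthesis gene unc-25 (7.40) and the acetylcholine genes unc-17 (7.37), cha-1 (7.11) and cho-1 (6.71). Of genes of ciliated sensory neurons 34 of 43 rose (36 over the list alone) (median 5.65, camera adjusted p = 3.48e-17, adjusted p = 0.147 with an estimated correlation), with dyf-11 (7.94), the G protein gene odr-3 (7.44) and the channel gene ocr-2 (5.89). Of chemoreceptor genes 68 of 154 rose (71 over the list alone) (median 3.86, camera adjusted p = 1.26e-19, adjusted p = 0.171 with an estimated correlation). Among the largest rises were the homeobox genes ceh-9 (log2 9.60, SE 0.84) and ceh-23 (8.93), with talp-3 (8.98) and mec-9 (8.77).

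Genes of other tissues fell in the neurons A IP. Of germline and oocyte genes 28 of 50 fell (39 over the list alone), with cpg-2 (-3.17), cpg-1 (-3.11) and spn-4 (-3.98). Of major sperm protein genes 24 of 29 fell (28 over the list alone). Of intestinal genes 1 of 31 rose and 15 fell (1 and 17 over the list alone), with asp-1 (-2.52), and nep-17 fell to log2 -2.24, while vit-5 gave -1.79 without passing (adjusted p = 0.055). The muscle genes myo-3 (-2.16) and pat-10 (-3.50) fell. Of collagens 3 rose and 48 fell (3 and 71 over the list alone), with col-119 (-2.94), and of mitochondrially encoded mRNAs 7 of 12 fell (9 over the list alone). The germline, sperm protein, intestine, collagen and mitochondrial lists had camera adjusted p from 6.21e-11 to 0.000762, and adjusted p from 0.253 to 0.535 with an estimated correlation. Large falls included the catalase gene ctl-1 (log2 -7.50, SE 1.39), ule-2 (-6.27), bath-30 (-6.08) and the replication origin gene orc-5 (-6.0). limma called 2213 genes risen and 1738 fallen of 14483, and 2851 and 3295 with replicates as a block. Neurons A IP replicate 3 stood apart, with 7896 genes at 0 (44%) and a correlation with the other replicates from 0.644 across genes. The total was 7540 without that library, 2299 without total RNA replicate 3, 0 without replicate 1 and 123 without replicate 2.

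In neurons B, rab-3 rose from 389 ± 212 to 26610 ± 4817 (log2 6.21, SE 0.35, adjusted p = 1.88e-07, n = 3 per group). sbt-1 stood at 324800 ± 71710 against 1901 ± 483 (log2 7.42, SE 0.31), and the peptide processing genes egl-21 (log2 6.59, SE 0.37), egl-3 (log2 5.97, SE 0.47) and the dense core vesicle gene ida-1 (6.23) rose with it. Of neuropeptide genes 69 of 69 rose (69 over the list alone) (median 7.13, camera adjusted p = 3.97e-25, adjusted p = 0.303 with an estimated correlation), with flp-1 (8.53), flp-14 (7.39), flp-9 (7.38) and pdf-1 (7.32). The largest rises included the insulin-like genes ins-25 (log2 9.58, SE 0.65), ins-10 (9.13) and ins-29 (9.04), together with hot-3 (9.09), cwp-1 (8.93), nlp-41 (8.88), nlp-50 (8.62) and degl-2 (8.84). Of chemoreceptor genes 434 of 453 rose and 3 fell (434 and 3 over the list alone) (median 4.82, camera adjusted p = 6.53e-21, adjusted p = 0.229 with an estimated correlation). In both strains the filter on means included the IP, favouring chemoreceptors that rose. Of ciliated sensory neuron genes 42 of 43 rose (42 over the list alone), with dyf-11 (5.72), osm-10 (5.18) and the diacetyl receptor gene odr-10 (4.51). Of pan-neuronal genes 33 of 35 rose and 1 fell (33 and 1 over the list alone), and of neurotransmitter genes 16 of 18 rose and 1 fell (16 and 1 over the list alone), with cho-1 (7.77), unc-17 (7.45) and unc-25 (7.26). These last 3 lists had camera adjusted p from 1.6e-12 to 2.26e-06, and adjusted p from 0.229 to 0.348 with an estimated correlation.

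Intestinal transcripts rose in the neurons B IP as well: 23 of 33 rose (22 over the list alone) (median 1.28, camera adjusted p = 0.00194, adjusted p = 0.563 with an estimated correlation). Their most abundant members did not pass, with vit-2 at log2 1.25 (adjusted p = 0.119) and vit-3 at 1.33 (adjusted p = 0.0646), and nep-17 gave 0.75 (adjusted p = 0.0568). Of lectin and lysozyme genes 93 of 177 rose and 22 fell (91 and 22 over the list alone), a list with camera adjusted p = 0.0223 and adjusted p = 0.502 with an estimated correlation, including spp-5 (log2 2.80, SE 0.41), spp-14 (2.51), ilys-5 (2.17) and clec-63 (1.27). Germline transcripts fell: 50 of 50 fell (50 over the list alone) (median -2.43, camera adjusted p = 3.56e-14, adjusted p = 0.383 with an estimated correlation), with car-1 (-2.65), cbd-1 (-2.67) and cpg-1 (-2.52), and of the GLD-1 targets 17 of 17 fell (17 over the list alone), with spn-4 (-3.13). Of major sperm protein genes 28 of 28 fell (28 over the list alone), and of mitochondrially encoded mRNAs 12 of 12 fell (12 over the list alone). Of body wall muscle genes 8 of 35 rose and 21 fell (8 and 21 over the list alone), with myo-3 (-2.44), the myosin gene unc-54 (-2.38), pat-10 (-2.17) and the tropomyosin gene lev-11 (-1.92). Of epidermal and cuticle genes 1 of 39 rose and 34 fell (1 and 34 over the list alone), with col-119 (-2.12) and lin-26 (-2.43). Of translation factor genes 4 of 41 rose and 23 fell (4 and 22 over the list alone), with eef-1B.1 (-1.27) and eef-1G (-1.02). The GLD-1, sperm protein, mitochondrial, muscle, epidermal and translation factor lists had camera adjusted p from 1.26e-08 to 0.00359, and adjusted p from 0.229 to 0.516 with an estimated correlation. Large falls included sdz-27 (log2 -4.64, SE 0.37), col-117 (-4.48) and ule-2 (-4.21). limma called 6420 genes risen and 5409 fallen of 16572.

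The soma comparison asked for ribosome-bound transcripts of all somatic tissue. nlp-27, an epidermal antimicrobial peptide gene, rose from 7783 ± 1671 to 61700 ± 10130 (log2 3.00, SE 0.26, adjusted p = 0.000862, n = 3 per group), and nlp-33 (2.92) and nlp-30 (2.85) of the same family rose. drd-10 (WBGene00016361, chromosome V, 7007607 to 7008299) rose from 499 ± 194 to 4754 ± 1532 (log2 3.28, SE 0.37). Of neuropeptide genes 62 of 68 rose (63 over the list alone) (median 1.59, camera adjusted p = 2.77e-16, adjusted p = 0.39 with an estimated correlation), with nlp-36 (2.37), flp-1 (2.20) and nlp-40 (1.70). Of intestinal genes 25 of 33 rose (27 over the list alone) (median 1.3, camera adjusted p = 2.96e-09, adjusted p = 0.0552 with an estimated correlation), with dct-16 at 2.52. Of collagens 69 of 120 rose (69 over the list alone), with col-122 (1.64) and col-119 (1.22). Of epidermal and cuticle genes 24 of 39 rose and 3 fell (25 and 4 over the list alone), with col-19 (1.08). Of lectin and lysozyme genes 84 of 184 rose and 12 fell (82 and 10 over the list alone), with spp-5 (2.75), spp-14 (2.16), ilys-5 (1.73) and lys-4 (1.71). Of pharyngeal genes 10 of 19 rose (10 over the list alone), with the troponin genes tnc-2 (2.47), tnt-4 (1.91) and tni-4 (1.77). Of body wall muscle genes 15 of 35 rose and 2 fell (14 and 2 over the list alone), with mlc-1 (1.66), pat-10 (1.49) and mlc-2 (1.32), although myo-3 fell (log2 -1.18, adjusted p = 0.0165). Of proton pump genes 13 of 21 rose and 1 fell (15 and 1 over the list alone), with vha-10 (1.51). These last 6 lists had camera adjusted p from 2.09e-11 to 0.00245, and adjusted p from 0.146 to 0.451 with an estimated correlation. rab-3 rose to log2 0.85 (adjusted p = 0.0421).

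The translation elongation factor gene eef-1A.1 (WBGene00001168, chromosome III, 6970026 to 6971712), also called eft-3, whose promoter drove the tag, fell in the soma IP from 528600 ± 112700 to 203500 ± 72450 (log2 -1.43, SE 0.29, adjusted p = 0.00249). Cytosolic ribosomal protein genes fell with it: 1 of 83 rose and 75 fell (1 and 76 over the list alone) (median -1.28, camera adjusted p = 4.77e-12, adjusted p = 0.424 with an estimated correlation), including rps-23 (-1.65), rps-25 (-1.42) and rpl-3 (-1.10). Of translation factor genes 0 of 41 rose and 31 fell (1 and 32 over the list alone), with eef-1G (-1.66) and eef-2 (-0.94), and of proteasome genes 28 of 31 fell (28 over the list alone), with pas-3 (-1.24). Germline transcripts fell: 1 of 50 rose and 48 fell (1 and 48 over the list alone) (median -2.26, camera adjusted p = 9.66e-14, adjusted p = 0.39 with an estimated correlation), with cpg-2 (-2.40), cgh-1 (-2.25) and car-1 (-1.93), whereas perm-2 (1.07) rose. Of GLD-1 targets 17 of 17 fell (17 over the list alone), with puf-5 (-2.44). Of major sperm protein genes 28 of 28 fell (28 over the list alone), and of mitochondrially encoded mRNAs 12 of 12 fell (12 over the list alone). Of histone genes, many of them near-identical, 7 of 60 rose and 30 fell (7 and 30 over the list alone), with the linker histone gene hil-4 (-2.27). The translation factor, proteasome, GLD-1, sperm protein, mitochondrial and histone lists had camera adjusted p from 1.13e-07 to 0.00618, and adjusted p from 0.39 to 0.464 with an estimated correlation. Large falls included gln-5 (log2 -3.30, SE 0.40), the catalase gene ctl-3 (-3.26), the meiotic gene pch-2 (-3.17) and the spermatogenesis gene spe-44 (-2.99). limma called 4030 genes risen and 5236 fallen of 16031.

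The ubiquitous comparison asked what an IP from all cells holds beside total RNA. The 12 mitochondrially encoded mRNAs, which cytosolic ribosomes do not translate, fell furthest as a group: 12 of 12 fell (12 over the list alone) (median -5.93, camera adjusted p = 4.6e-17, adjusted p = 0.882 with an estimated correlation). The long noncoding RNAs tts-1 (log2 -3.58, SE 0.58), rncs-1 (log2 -3.35, SE 0.44) and lep-5 (-2.79) fell (n = 3 per group). The replication protein gene rpa-4 (WBGene00019079, chromosome I, 5509467 to 5511705) rose from 48.5 ± 21.4 to 355 ± 21.7 (log2 2.93, SE 0.27, adjusted p = 6.74e-05), and the nuclear receptor gene nhr-114 rose from 1190 ± 297 to 6522 ± 532 (log2 2.48, SE 0.18). Further rises were pqn-15 (2.29), taf-3 (2.23) and che-10 (1.86). pud-1.1 stood at 909 ± 101 in the IP and was listed at 0 in total RNA, where a near-identical copy makes the assignment uncertain. Of germline and oocyte genes 4 of 50 rose and 23 fell (4 and 25 over the list alone), with cpg-2 (-1.35) and cgh-1 (-1.25), and of GLD-1 targets 11 of 17 fell (12 over the list alone), with puf-5 (-1.60) and the yolk receptor gene rme-2 (-1.01). Of proton pump genes 15 of 21 fell (16 over the list alone), with vha-13 (-1.18) and vha-8 (-0.74). Of translation factor genes 1 of 41 rose and 17 fell (1 and 17 over the list alone). These 4 lists had camera adjusted p from 2.78e-05 to 0.000549, and adjusted p = 0.882 with an estimated correlation. Of cytosolic ribosomal protein genes 1 of 83 rose and 3 fell (0 and 0 over the list alone), and the list did not pass (camera adjusted p = 0.487), with a median of -0.17 that equal-sum scaling turned to 0.08. Genes known from single tissues that passed included vit-2 (0.69), mlc-2 (0.93), tni-4 (0.66), nlp-27 (1.07) and the transport gene osm-1 (1.48) upward and nep-17 (-0.95) and act-4 (-0.94) downward. limma called 2344 genes risen and 2832 fallen of 13853. The total was 2620 without replicate 1, 2037 without replicate 2 and 6342 without replicate 3. Equal-sum scaling called 2227 risen and 1032 fallen (68.3% risen against 45.3%).

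**Figure D1:**
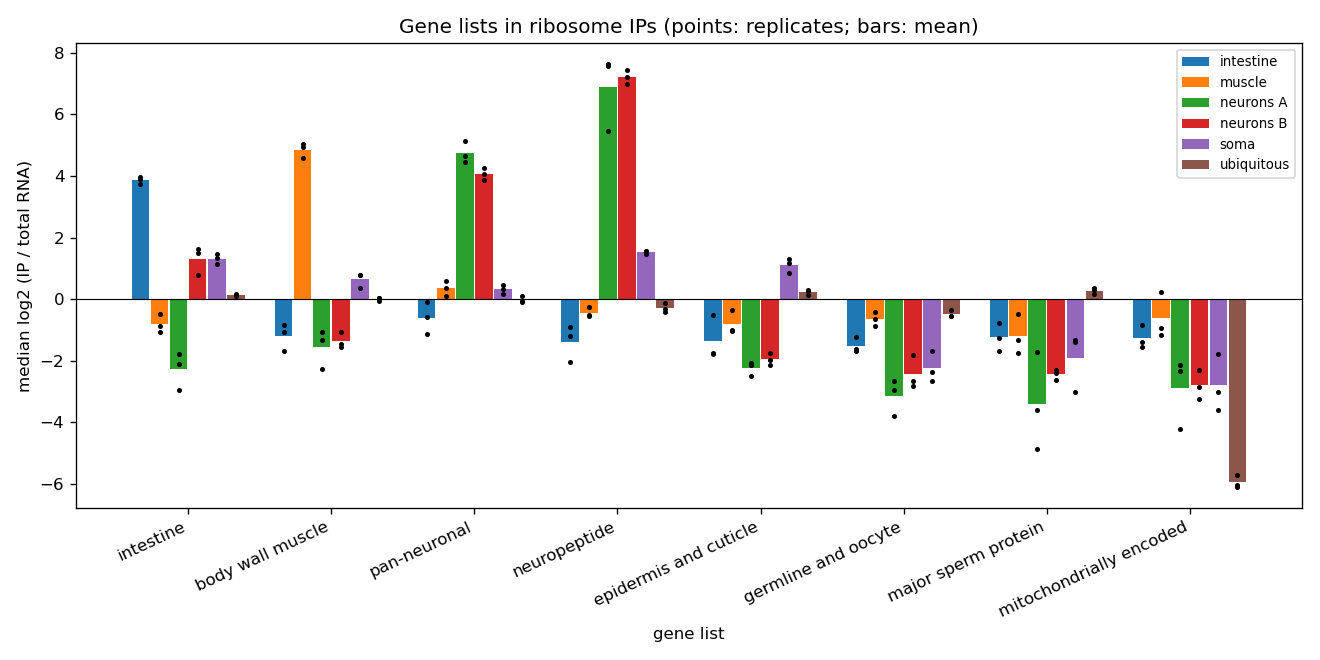
Median log2 ratio of IP over total RNA for 8 gene lists in the 6 IP experiments. Each point is the median over a list's genes in 1 replicate and each bar is the mean of the 3 replicates. The intestine, muscle and neuronal lists stand highest in the strains whose promoters name them, and the mitochondrially encoded mRNAs lie lowest in the ubiquitous IP (-5.92 over all members). Equal-sum scaling turns the pan-neuronal medians of the muscle and ubiquitous IPs to the opposite sign and no other median shown.

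Polysomes of the ubiquitous strain asked which transcripts were on actively translating ribosomes without an IP. Cytosolic ribosomal protein genes rose: 74 of 83 rose and 2 fell (75 and 2 over the list alone) (median 1.22, camera adjusted p = 1.75e-10, adjusted p = 0.524 with an estimated correlation), with rpl-2 at 267400 ± 85580 against 110900 ± 26670 (log2 1.25, SE 0.31, adjusted p = 0.00749, n = 3 per group), rpl-3 (1.12) and rpl-4 (1.02). Of major sperm protein genes 28 of 29 rose and 1 fell (28 and 1 over the list alone) (median 1.73, camera adjusted p = 3.61e-10, adjusted p = 0.473 with an estimated correlation). Of collagens 88 of 111 rose and 2 fell (89 and 2 over the list alone), with col-122 (1.35) and col-119 (1.21). Of lectin and lysozyme genes 88 of 132 rose and 8 fell (92 and 8 over the list alone), with spp-5 (1.97) and ilys-5 (1.76), although clec-87 (-2.43) fell. Of intestinal genes 27 of 32 rose (28 over the list alone), of mitochondrial ribosomal protein genes 44 of 70 rose (44 over the list alone), with mrpl-12 (1.38), and of oxidative phosphorylation genes 24 of 32 rose and 1 fell (24 and 1 over the list alone), with atp-2 (0.89). These last 5 lists had camera adjusted p from 1.37e-10 to 8.4e-06, and adjusted p from 0.473 to 0.524 with an estimated correlation. Large rises included drd-10 (log2 2.38, SE 0.35), nlp-27 (log2 2.16, SE 0.29), ins-27 (2.10), spp-23 (2.07) and spp-1 (2.02).

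The long noncoding RNA tts-1 (WBGene00006650, chromosome X, 1504131 to 1504841) fell from 237 ± 10.3 in total RNA to 15.9 ± 3.68 in polysomes (log2 -3.84, SE 0.24, adjusted p = 5.17e-05). The nanos gene nos-2 fell from 5464 ± 266 to 409 ± 99.8 (log2 -3.77, SE 0.21) and so did the caudal gene pal-1 (log2 -3.40, SE 0.33). Of GLD-1 targets 17 of 17 fell (17 over the list alone) (median -1.74, camera adjusted p = 7.21e-07, adjusted p = 0.473 with an estimated correlation), with puf-5 (-1.91), rme-2 (-1.64), cpg-2 (-1.59) and cpg-1 (-1.53). Of germline and oocyte genes 2 of 50 rose and 39 fell (2 and 39 over the list alone), with cbd-1 (-1.94), and of mitochondrially encoded mRNAs 12 of 12 fell (12 over the list alone). Both lists passed (camera adjusted p from 2.99e-07 to 5.11e-07), with adjusted p = 0.473 with an estimated correlation. Other large falls were gap-3 (-3.38), pak-2 (-3.35) and mys-4 (-3.25). limma called 4158 genes risen and 4440 fallen of 14651. Equal-sum scaling left 2968 risen and 4917 fallen (37.6% risen against 48.4%).

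In the pooled 60S, 80S and polysome fractions the same question was put to all ribosome-bound RNA. tts-1 fell from 595 ± 12.4 to 73.6 ± 6.26 (log2 -3.0, SE 0.16, adjusted p = 1.95e-07, n = 3 per group), and nos-2 fell from 7751 ± 786 to 1597 ± 225 (log2 -2.28, SE 0.15). tts-2 (-2.21), pal-1 (-2.20), gmn-1 (-2.18), the phosphatase gene cdc-25.3 (-2.16) and lin-7 (-2.15) fell with them. Of major sperm protein genes 28 of 29 rose (28 over the list alone) (median 0.98, camera adjusted p = 3.13e-14, adjusted p = 0.684 with an estimated correlation). Of cytosolic ribosomal protein genes 41 of 83 rose and 2 fell (48 and 2 over the list alone) (median 0.50, camera adjusted p = 4.4e-08, adjusted p = 0.878 with an estimated correlation), with rpl-2 (0.56). Of GLD-1 targets 15 of 17 fell (17 over the list alone), with puf-5 (-0.97), and of germline and oocyte genes 1 of 50 rose and 31 fell (1 and 35 over the list alone), with cpg-2 (-0.57). Of mitochondrially encoded mRNAs 10 of 12 fell (10 over the list alone), and of histone genes 4 of 54 rose and 32 fell (5 and 33 over the list alone), with hil-5 (-1.13). These 4 lists had camera adjusted p from 5.46e-07 to 7.97e-05, and adjusted p from 0.684 to 0.748 with an estimated correlation. Rises were txt-14 (log2 1.75, SE 0.17), which stood at 555 ± 29.6 against 166 ± 31.9, drd-10 (1.65), grsp-3 (1.53), the synaptobrevin gene snb-6 (1.44), nlp-27 (1.41) and spp-5 (1.20). limma called 3049 genes risen and 3423 fallen of 14824.

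Wild-type polysomes asked the same without a tag. tts-1 fell from 349 ± 98.6 to 17.1 ± 8.44 (log2 -4.36, SE 0.33, adjusted p = 4.78e-08, n = 3 per group), nos-2 from 5950 ± 754 to 675 ± 86 (log2 -3.14, SE 0.13), and the large falls also took in dnj-26 (-3.32), the importin gene ima-1 (-3.17), fbxa-215 (-3.09), cdc-25.3 (-3.08) and rsa-1 (-3.01). Of cytosolic ribosomal protein genes 75 of 83 rose and 2 fell (75 and 2 over the list alone) (median 1.29, camera adjusted p = 8.68e-14, adjusted p = 0.463 with an estimated correlation), with rpl-2 (1.39) and rpl-3 (1.29). The elongation factor genes eef-1A.1 (log2 1.09, SE 0.21) and eef-2 (log2 0.97, SE 0.19) and the eIF5A gene iff-1 (1.78) rose. Of collagens 101 rose and 2 fell (101 and 2 over the list alone), with col-122 (1.65) and col-119 (1.58), and of major sperm protein genes 28 of 29 rose and 1 fell (28 and 1 over the list alone). Of GLD-1 targets 17 of 17 fell (17 over the list alone), with puf-5 (-1.35) and rme-2 (-1.10), of germline and oocyte genes 6 of 50 rose and 38 fell (7 and 39 over the list alone), with cbd-1 (-1.16) and cpg-2 (-0.93), and of mitochondrially encoded mRNAs 12 of 12 fell (12 over the list alone). These 5 lists had camera adjusted p from 1.87e-13 to 2.63e-06, and adjusted p = 0.463 with an estimated correlation. nlp-27 rose from 2108 ± 118.5 to 10040 ± 1214 (log2 2.25, SE 0.12), and cnc-10 (2.23), spp-23 (2.22), vit-6 (1.00), ilys-5 (1.91) and pat-10 (1.34) rose. limma called 4941 genes risen and 4989 fallen of 14705. Equal-sum scaling left 3018 risen and 6413 fallen (32% risen against 49.8%).

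**Figure D2:**
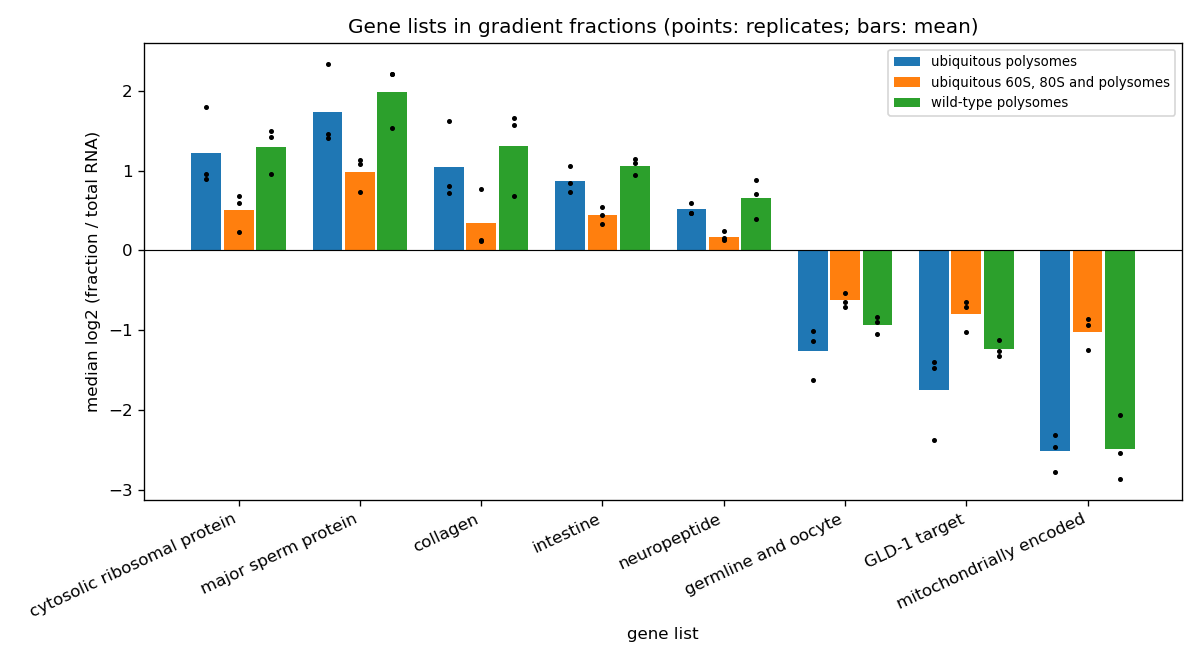
Median log2 ratio of gradient fraction over total RNA for 8 gene lists in the 3 gradient experiments. Each point is the median over a list's genes in 1 replicate and each bar is the mean of the 3 replicates. Ribosomal protein, major sperm protein and collagen genes lie above 0 and germline, GLD-1 target and mitochondrially encoded genes below 0 in each of the 3, and equal-sum scaling turns none of the medians shown to the opposite sign.

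Differences between experiments were tested as the log2 ratio of the first experiment minus that of the second, over 12 libraries. The list tests of these differences were added after the data had been seen, and the first 5 share the 6 ubiquitous libraries. Against the ubiquitous IP, the intestine IP was higher by log2 4.26 for nep-17 (SE 0.38, adjusted p = 1.12e-05), by 7.52 for cah-4 (SE 0.61) and by 6.77 for cpf-1. The lectin gene clec-41 (log2 6.19, SE 0.34), the haem transport gene hrg-4 (5.91) and the glutathione transferase gene gst-6 (5.85) were higher too. Of the intestine list 31 of 33 were higher (31 over the list alone) (median 3.84, camera adjusted p = 7.19e-18, adjusted p = 0.00176 with an estimated correlation), with vit-5 (3.41) and dct-16 (4.88). Of lectin and lysozyme genes 73 of 111 were higher and 4 were lower (74 and 7 over the list alone) (median 4.24, camera adjusted p = 5.53e-16, adjusted p = 0.0995 with an estimated correlation), with spp-5 (4.59). vha-6 (4.43), cat-4 (4.98) and nlp-36 (3.76) were higher. rmd-3 (-4.65), the collagen gene col-120 (-3.47) and the myosin gene mlc-2 (-2.68) were lower. rpl-22 differed by -0.06 (SE 0.45, adjusted p = 0.923). limma called 2338 genes higher and 1147 lower of 12474, with 2937 and 2369 when replicates were blocked, and 1081 in all without replicate 1. Equal-sum scaling called 1115 higher and 5721 lower (16.3% higher against 67.1%).

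Against the ubiquitous IP, the muscle IP was higher for myo-3 by 3.81 (SE 0.25, adjusted p = 7.02e-09), pat-10 by 6.64 (SE 0.54) and act-4 by 6.05 (SE 0.33). Of the body wall muscle list 35 of 35 were higher (35 over the list alone) (median 4.83, camera adjusted p = 5.56e-26, adjusted p = 0.159 with an estimated correlation). The transthyretin-like gene ttr-24 (log2 6.85, SE 0.43), cpg-9 (6.83) and the potassium channel gene twk-18 (6.41) were higher. Of oxidative phosphorylation genes 29 of 32 were higher and 1 were lower (29 and 1 over the list alone) (median 2.67, camera adjusted p = 1.13e-12, adjusted p = 0.522 with an estimated correlation). The cytochrome c gene cyc-2.2 (-2.43) and vit-2 (-1.45) were lower. rpl-22 was higher by 1.44 (SE 0.48, adjusted p = 0.0261), which equal-sum scaling turned to -0.19. limma called 3498 genes higher and 1979 lower of 13443, and the total was 2641 without replicate 2 and 3619 without replicate 3. Equal-sum scaling called 1207 higher and 9204 lower (11.6% higher against 63.9%).

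Neurons A was higher than the ubiquitous IP for rab-3 by 5.95 (SE 1.05, adjusted p = 0.00237), sbt-1 by 7.20 (SE 0.50) and egl-3 by 7.29 (SE 0.46). The acetylcholine receptor gene acr-2 (log2 9.06, SE 1.02), nlp-9 (8.91) and cpx-1 (8.82) were higher. Of pan-neuronal genes 22 of 35 were higher (23 over the list alone) (median 4.79, camera adjusted p = 5.61e-17, adjusted p = 0.013 with an estimated correlation), of neuropeptide genes 64 of 67 were higher and 1 were lower (64 and 1 over the list alone) (median 7.19, camera adjusted p = 9.8e-45, adjusted p = 0.129 with an estimated correlation), and of ciliated sensory neuron genes 13 of 17 were higher (15 over the list alone) (median 4.43, camera adjusted p = 6.95e-10, adjusted p = 0.00407 with an estimated correlation). ctl-1 (log2 -8.55, SE 1.43) and myo-3 (-1.76) were lower, and of germline and oocyte genes 23 of 50 were lower (29 over the list alone) (median -2.65, camera adjusted p = 7.73e-08, adjusted p = 0.285 with an estimated correlation). limma called 1602 genes higher and 2178 lower of 12971, and 2173 and 3602 when replicates were blocked. The total was 6980 without neurons A IP replicate 3, 134 without replicate 1 and 746 without replicate 2, and with equal-sum scaling 26.6% of called genes were higher against 42.4%.

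Neurons B was higher than the ubiquitous IP for rab-3 by 6.09 (SE 0.43, adjusted p = 2.22e-08), flp-1 by 8.43 (SE 0.29) and unc-17 by 7.68. nlp-17 (log2 9.74, SE 0.47), ins-10 (9.22) and lury-1 (8.97) were higher. Of neuropeptide genes 67 of 67 were higher (67 over the list alone) (median 7.55, camera adjusted p = 2.29e-37, adjusted p = 0.126 with an estimated correlation). Of intestinal genes 23 of 33 were higher (23 over the list alone) (median 1.35, camera adjusted p = 0.000824, adjusted p = 0.471 with an estimated correlation), with nep-17 higher by 1.70 (adjusted p = 0.0014), and spp-5 was higher by 2.35. col-117 (log2 -4.58, SE 1.56), car-1 (-2.75) and mlc-2 (-3.0) were lower, and of germline and oocyte genes 45 of 50 were lower (46 over the list alone) (median -2.07, camera adjusted p = 2.98e-10, adjusted p = 0.455 with an estimated correlation). limma called 4049 genes higher and 4239 lower of 13286, and 5521 in all without replicate 2. With equal-sum scaling 32.9% of called genes were higher against 48.9%.

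The soma IP was higher than the ubiquitous IP for nlp-17 (log2 3.51, SE 0.61), lury-1 (log2 3.19, SE 0.44), the transthyretin-like gene ttr-27 (2.95), tnc-2 (2.69), spp-5 (2.30) and nep-17 (1.48). Of neuropeptide genes 60 of 67 were higher (61 over the list alone) (median 1.81, camera adjusted p = 8.63e-23, adjusted p = 0.258 with an estimated correlation) and of intestinal genes 21 of 33 were higher (23 over the list alone) (median 1.34, camera adjusted p = 2.1e-08, adjusted p = 0.0638 with an estimated correlation). rpa-4 (log2 -4.84, SE 0.41), cyc-2.2 (-3.86), car-1 (-2.03) and hil-4 (-2.17) were lower, of germline and oocyte genes 40 of 50 were lower (41 over the list alone) (median -1.83, camera adjusted p = 1.46e-09, adjusted p = 0.475 with an estimated correlation), and of cytosolic ribosomal protein genes 41 of 83 were lower (43 over the list alone) (median -1.12, camera adjusted p = 1.22e-06, adjusted p = 0.556 with an estimated correlation). eef-1A.1 differed by -0.92 (SE 0.40, adjusted p = 0.0699) without passing. limma called 2781 genes higher and 4000 lower of 13764, with 3840 in all without replicate 1 and 3906 without replicate 2. With equal-sum scaling 32.4% of called genes were higher (1987 and 4138) against 41%.

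The mitochondrially encoded mRNAs, lowest in the ubiquitous IP, were higher than there in all 5 of these IPs. In the intestine IP 12 of 12 were higher (12 over the list alone) (median 4.69, camera adjusted p = 5.48e-11, adjusted p = 0.115 with an estimated correlation). Medians were 5.19 in muscle, 2.91 in neurons A, 3.28 in neurons B and 3.21 in soma. In neurons A 8 of 12 were higher (9 over the list alone), and in the others 12 of 12 by either count. Camera adjusted p lay from 5.48e-11 to 1.34e-05 over the 5 differences, and the adjusted p from 0.115 to 0.522 with an estimated correlation.

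Neurons A against neurons B compared the 2 strains tagged from the rab-3 promoter. Of pan-neuronal genes 0 of 35 were called by limma (0 over the list alone) (median 0.77, camera adjusted p = 5.27e-06, adjusted p = 0.217 with an estimated correlation). Not passing were rab-3 at -0.14 (SE 1.09, adjusted p = 0.968), sbt-1 at -0.21 (SE 0.58, adjusted p = 0.899) and unc-25 at 0.13 (SE 0.59, adjusted p = 0.938). Intestinal genes were lower in neurons A: 15 of 31 were lower (30 over the list alone) (median -3.67, camera adjusted p = 8.04e-25, adjusted p = 0.107 with an estimated correlation), with vit-5 at -2.94 (adjusted p = 0.0468). Of lectin and lysozyme genes 0 of 124 were higher and 31 were lower (1 and 68 over the list alone) (median -3.31, camera adjusted p = 3.93e-21, adjusted p = 0.0973 with an estimated correlation), with lys-6 (-7.03) and spp-5 (-4.27). The catalase gene ctl-1 (log2 -9.15, SE 1.38), drd-5 (-6.94) and the transthyretin-like gene ttr-37 (-6.40) were lower as well. Across 13938 genes the 2 log2 ratios had Pearson r = 0.853, where genes are not independent replicates. 2180 genes rose in both strains, against 849 by independent lists, and 176 were called in opposite directions. limma called 2 genes higher, both named here after their values were seen, Y48C3A.12 (log2 3.12, SE 0.71) and T23C6.4 (log2 3.00, SE 0.59), and 332 lower. With replicates blocked 46 were higher and 462 lower, and without replicate 1 or without replicate 2 the count was 0 (limma, with 1695 genes at an unadjusted p under 0.05 on all libraries and 1252 by the authors' statistics). The count was 976 without neurons A IP replicate 3, 754 without replicate 3 and 182 without neurons A total RNA replicate 3.

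The ubiquitous IP against polysomes of the same strain compared the 2 ways of collecting ribosomes. rpa-4 was higher in the IP by 5.27 (SE 0.35, adjusted p = 6.21e-07), having risen by 2.93 in the IP and stood at -2.34 in polysomes. math-3 (log2 5.05, SE 0.45), mys-4 (3.53), the splicing gene rbm-25 (3.10) and nhr-114 (3.06) were higher in the IP. Cytosolic ribosomal protein genes were lower in the IP: 1 of 83 was higher and 65 lower (1 and 72 over the list alone) (median -1.32, camera adjusted p = 9.15e-11, adjusted p = 0.469 with an estimated correlation), with rps-8 (-1.72) and rpl-2 (-1.08). The list was not tested without ubiquitous total RNA replicate 3. Of mitochondrially encoded mRNAs 12 of 12 were lower (12 over the list alone) (median -3.86, camera adjusted p = 2.23e-10, adjusted p = 0.426 with an estimated correlation), and of major sperm protein genes 28 of 29 were lower (28 over the list alone) (median -1.55, camera adjusted p = 2.39e-08, adjusted p = 0.426 with an estimated correlation). Of GLD-1 targets 11 of 17 were higher (13 over the list alone) (median 1.24, camera adjusted p = 0.000347, adjusted p = 0.459 with an estimated correlation), with cpg-1 (0.88), and cbd-1 (1.50) was higher too. spp-17 (log2 -2.68, SE 0.51), bath-5 (-2.34), eef-1A.1 (-1.26) and atp-2 (-1.37) were lower. The log2 ratios of the 2 experiments had r = 0.284 across 13662 non-independent genes, and 837 genes were called in opposite directions. limma called 3071 genes higher and 3080 lower, with 3842 in all without replicate 2 and 3137 without replicate 3. Equal-sum scaling called 3728 higher and 1236 lower (75.1% higher against 49.9%).

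Against the pooled fractions the ubiquitous IP was higher for rpa-4 (log2 3.95, SE 0.30), math-3 (log2 3.07, SE 0.39), nhr-114 (2.73), the noncoding RNA linc-9 (2.46), nhr-5 (2.42) and the axin gene pry-1 (2.14). nlp-17 (log2 -2.40, SE 0.50), bath-5 (-2.21), clec-41 (-2.19) and ubl-5 (-2.04) were lower. Of mitochondrially encoded mRNAs 12 of 12 were lower (12 over the list alone) (median -5.13, camera adjusted p = 8.04e-23, adjusted p = 0.233 with an estimated correlation), and of mitochondrial ribosomal protein genes 1 of 70 were higher and 30 were lower (2 and 42 over the list alone) (median -0.61, camera adjusted p = 3.82e-08, adjusted p = 0.669 with an estimated correlation). rpl-22 differed by 0.05 (SE 0.38, adjusted p = 0.942). The log2 ratios had r = 0.414 across 13685 genes. limma called 1612 genes higher and 1631 lower, 1505 in all without replicate 1 and 582 without replicate 2. Equal-sum scaling called 1204 higher and 491 lower (71.0% higher against 49.7%).

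Polysomes against the pooled fractions asked what the heavy fractions hold beyond all ribosomes. fbxa-216 (log2 -2.20, SE 0.33), math-3 (-1.98), the kinase gene mtk-1 (-1.96) and the Argonaute gene alg-5 (-1.80) were lower in polysomes, and so was the yolk receptor gene rme-2 (-1.09). rpl-41.1 (-2.38) and rpl-41.2 (-2.39) were lower too, with near-identical sequences that leave their counts uncertain. Of mitochondrially encoded mRNAs 7 of 12 were lower (11 over the list alone) (median -1.54, camera adjusted p = 5.07e-08, adjusted p = 0.385 with an estimated correlation), and of GLD-1 targets 3 of 17 were lower (13 over the list alone) (median -1.01, camera adjusted p = 4.75e-07, adjusted p = 0.385 with an estimated correlation). msrp-4 (log2 1.24, SE 0.30), marg-1 (1.06) and phat-4 (1.06) were higher. As a list, cytosolic ribosomal protein genes lay higher (median 0.71, camera adjusted p = 6.96e-12, adjusted p = 0.39 with an estimated correlation), although 2 of 83 were lower (2 over the list alone). The log2 ratios had r = 0.861 across 14481 genes, with 2660 genes risen in both and 2994 fallen in both. limma called 73 genes higher and 871 lower, and 2 and 350 with replicates blocked. The total was 437 without replicate 1, 0 without replicate 2 and 3 without replicate 3 (limma, with 3891 genes at an unadjusted p under 0.05 on all libraries and 907 by the authors' statistics).

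Wild-type against ubiquitous-strain polysomes compared animals without and with the tag on RPL-22. rpl-22 differed by -0.12 (SE 0.37, adjusted p = 0.951), eef-1A.1 by 0.34 (SE 0.36, adjusted p = 0.813), myo-3 by 0.49 (SE 0.22, adjusted p = 0.74) and nep-17 by 0.44 (SE 0.24, adjusted p = 0.74). limma called 0 of 14372 genes, with 681 at an unadjusted p under 0.05 and 3 by a z test on the authors' statistics, and 1 gene without replicate 1. In each strain alone 3667 genes rose in both and 4097 fell in both, against 1406 and 1496 by independent lists, and 1 was called in opposite directions. The log2 ratios had r = 0.916 across genes. As a list, GLD-1 targets lay higher in wild type (median 0.62, camera adjusted p = 4.45e-05, adjusted p = 0.831 with an estimated correlation), with no member called, and germline and oocyte genes did too (median 0.38, camera adjusted p = 6.13e-06, adjusted p = 0.831 with an estimated correlation).

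**Figure D3:**
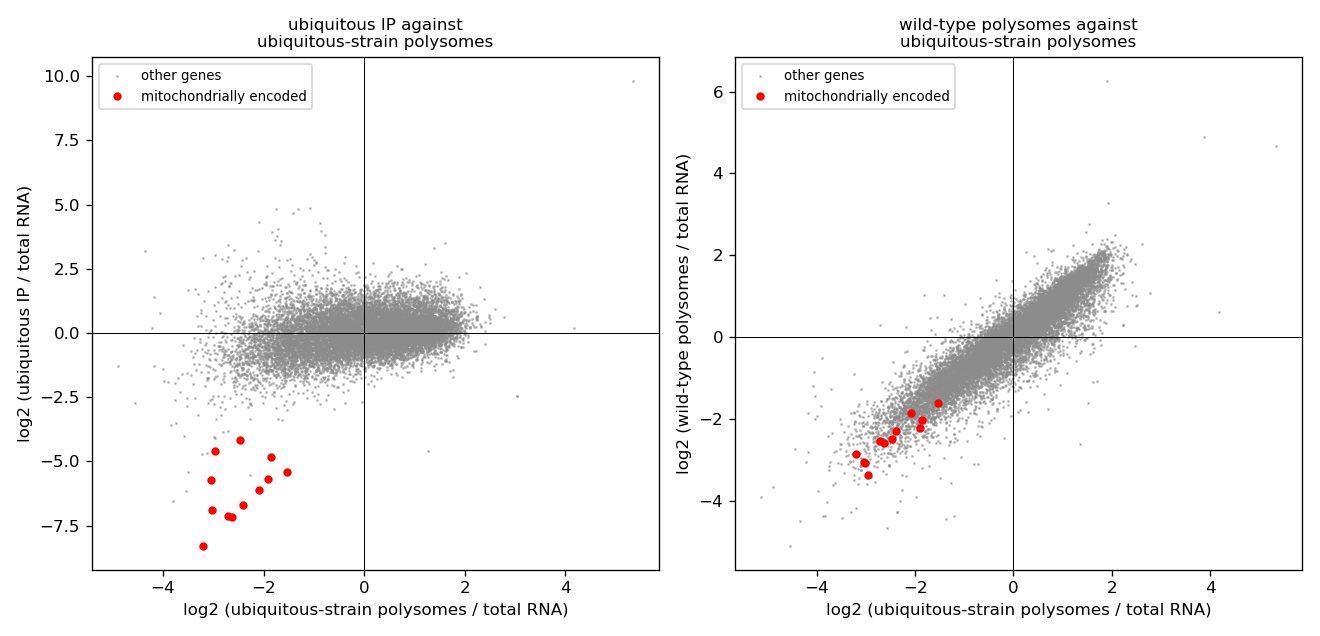
Log2 ratios over total RNA, gene by gene, of the ubiquitous IP against polysomes of the same strain (left) and of wild-type against ubiquitous-strain polysomes (right). Each point is 1 gene with a mean of at least 10 normalized counts in both experiments, and red points are the 12 mitochondrially encoded mRNAs. Pearson r across genes is 0.284 on the left and 0.916 on the right.

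Of all list calls with the preset correlation, 1 held with an estimated correlation among the single comparisons, the intestine list in the intestine IP. Among the differences the intestine list (intestine IP against ubiquitous IP), the pan-neuronal list and the ciliated neuron list (both neurons A against ubiquitous IP) held.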

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

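Chosen only after the results were seen were the tests of carry-over, of intestinal RNA, of normalization, of germline tagging, of replicate noise and of monosomes, the splits by pairs, the exchange of fraction and total RNA within an experiment, and the list tests of the differences. What singled out the results below was a difference between groups, in each case tested as the interaction of fraction and experiment. Groups of 3 libraries were not tested for a library far from the others.

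Genes with a different enrichment numbered 3485 for intestine against the ubiquitous IP, 5477 for muscle, 3780 for neurons A, 8288 for neurons B and 6781 for soma. Neurons A and neurons B differed at 334 genes. The ubiquitous IP differed from polysomes of its strain at 6151 genes and from the pooled fractions at 3243, and these 2 gradient fractions differed at 944. With an estimated inter-gene correlation, 3 list differences passed: intestine list, intestine against ubiquitous IP (median 3.84), and the pan-neuronal (median 4.79) and ciliated sensory neuron (median 4.43) lists, neurons A against ubiquitous IP.

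The real split and others were compared for every count. For each fraction against its total RNA, 10 splits of 6 libraries are too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes. The real counts were 3737 (intestine), 5311 (muscle), 3951 (neurons A), 11829 (neurons B), 9266 (soma), 5176 (ubiquitous), 8598 (ubiquitous polysomes), 6472 (pooled fractions) and 9930 (wild-type polysomes). The highest other split called 0 genes by limma, with 143 (ubiquitous polysomes) to 1046 (muscle) genes at an unadjusted p under 0.05.

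For the differences 100 splits were drawn. As many genes came from 1 split for intestine (real 3485, highest other 3106), muscle (5477 and 3244) and neurons B (8288 and 7633) against the ubiquitous IP, and for the ubiquitous IP against polysomes (6151 and 5348). They came from 2 splits for neurons A against the ubiquitous IP (3780 and 4748), neurons A against neurons B (334 and 3298) and the ubiquitous IP against the pooled fractions (3243 and 6787), and from 3 for soma (6781 and 8307). For these 8 counts the share was under 0.05 among the drawn splits, which ignore replicate numbers. Such splits also break up the effect of the fraction in each experiment, so they do not stand for equal enrichment in both. The share therefore does not decide whether chance gave these counts. A second set took all splits that part as many same-number pairs in intestine, neurons A and ubiquitous. There 2 of 32 splits, not a share under 0.05, were as large for intestine and for neurons A against the ubiquitous IP (highest other 5149 and 4748). The other split as large is in both cases the exchange described below, and without it the highest others were 3305 and 3717. For the other 6 counts 2 of 80 splits were as large, or 3 of 80 for neurons A against neurons B. For polysomes against the pooled fractions 7 of the 100 drawn splits were as large (944 and 9865), not a share under 0.05. For wild-type against ubiquitous-strain polysomes the splits decide nothing, since any of the 100 reaches the real count of 0 (limma; 681 genes at an unadjusted p under 0.05, 3 genes by the authors' statistics), and the highest other was 6495. Splits calling several times the real count point to a structure of the samples. Exchanging fraction and total RNA within 1 of the 2 experiments adds the 2 effects instead of subtracting them, and it called more genes than the real split in all 10 pairs. The counts ran from 4748 (neurons A and ubiquitous IP, real 3780) to 10743 (the 2 polysome experiments, real 0), with 7776 for neurons A and B. It was the only other drawn split as large for neurons A and ubiquitous IP (3717 without it) and for ubiquitous IP and pooled fractions (2450), while polysomes and pooled fractions still reached 7348 without it. It was not drawn for neurons A and B or for the 2 polysome experiments.

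Of the intestine list 23 of 33 genes rose in the neurons B IP and 1 of 31 in the neurons A IP, although abundant members did not pass, with vit-2 at log2 1.25 (adjusted p = 0.119) and vit-5 at 1.15 (adjusted p = 0.121) in neurons B. The tables argue against carry-over of bulk lysate, since the intestine list lay 3.71 above the germline list in neurons B. They also argue against neurons A IP replicate 3, the library with most genes at 0, as the source. Without it the median difference of the list was still -3.34, and 23 of 31 genes were lower (30 adjusted over the list alone). Ribosomes or RNA of the intestine are a candidate source: of 1690 genes at least 4-fold higher in the intestine than in the ubiquitous IP, intestine list left out, 69.6% rose in neurons B (38.7% of all tested genes), and 6.99% of 1587 rose in neurons A (15.3% of all). Whether the tag was made in the intestine of that strain, or intestine-tagged material was mixed in, stays open, and the series description gives neurons B and intestine the same strain name.

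Germline and mitochondrially encoded mRNAs fell by similar amounts within each tissue IP, with germline medians from -3.17 (neurons A) to -0.66 (muscle). Carry-over of untagged RNA stays open: of 13 medians of intestine, muscle, pharynx and epidermis lists in IPs of other tissues, intestine list in neurons B left out, 12 lay within 1 log2 of the germline median, but body wall muscle in neurons A lay 1.74 from it. Equal-sum scaling narrowed the span of the germline medians from 2.50 to 1.59, but a factor per library moves both lists nearly alike, so this leaves the authors' normalization open. Tagged ribosomes in the germline stay open too: the mitochondrial median lay no lower than -0.48 from the germline median in the tissue IPs and at -5.47 in the ubiquitous IP, but this gap is the pattern itself. A true difference between tissues in what the IP retains was not tested.

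The ubiquitous IP and polysomes of its strain had Pearson r = 0.284 across non-independent genes (0.412 at a mean of at least 100). Replicate noise alone would allow r up to 0.909. Offsets between experiments were not tested. Taking out a smooth trend on coding length moved r from 0.316 to 0.343 over 13190 genes. Monosomes and free large subunits stay open: the IP had r = 0.414 with the pooled fractions. The 0.861 of polysomes is no benchmark, as that pool holds them. No biological explanation was tested.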

How the results depend on the processing

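Equal-sum scaling, the authors' deposited tests and leaving out single libraries were chosen after the data had been seen, as were all list tests of differences, while the other alternatives were planned. The cause was not tested for any value given here. No filter on low values, pseudocount 0.5 and Spearman correlation kept each count within 1.5 times, or the median correlation within its spread.

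Whether replicate numbers pair fraction and total RNA stays uncertain: same-number deviations correlated above 0.1 throughout in 3 of 9 experiments, and of these not always best in neurons A. With a replicate block the counts were 6013 (intestine), 6146 (neurons A), 5306 (intestine against ubiquitous), 5775 (neurons A against ubiquitous), 508 (neurons A against B) and 352 (polysomes against pooled fractions), and 14 other results kept within 1.5 times. Pseudocount 5 moved 1 of 19 counts, neurons A against B, to 544.

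Equal-sum scaling gave 6993 (intestine), 12141 (muscle), 3259 (ubiquitous), 6836 (intestine against ubiquitous), 10411 (muscle against ubiquitous) and 1695 (ubiquitous IP against pooled fractions). It lowered the share of called genes that rose from 65.0% to 21.6% in intestine and from 63.8% to 13.9% in muscle. Among 499 values of the fixed genes, the largest changes and genes given in the text, 10 changed sign without a call under either scaling, and 4 changed sign with a call under at least 1: rab-3 in muscle (-0.72), and rpl-22 (-0.19), rab-3 (-1.08) and eef-1A.1 (-1.39) in muscle against ubiquitous. Under the other settings none of these did so with a call. Over 2267 values with all list members under the naming rule, 75 changed sign with a call under at least 1 scaling, 6 of them under both.

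The authors' statistics gave 7210 (intestine), 8372 (neurons A), 5735 (intestine against ubiquitous), 6590 (neurons A against ubiquitous), 1252 (neurons A against B) and 3 (wild-type against ubiquitous-strain polysomes). In the single comparisons list calls numbered 145 with the preset correlation and 1 with an estimated one. The median correlation between experiments rose from 0.259 to 0.414 over genes with a mean of at least 100.

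Leaving out a replicate or library gave 1029 (without replicate 1) to 4743 for intestine, 2725 (without replicate 3) to 8751 (without replicate 1) for muscle, and 0 (without replicate 1) to 9493 (without replicate 3) for neurons A. It gave 9031 to 12892 for neurons B, 6531 to 7982 for soma, 2037 (without replicate 2) to 6342 for ubiquitous, 5838 to 8571 for ubiquitous polysomes, 4661 to 5643 for pooled fractions and 7991 to 10593 for wild-type polysomes. Against the ubiquitous IP the ranges were 1081 (without replicate 1) to 5069 for intestine, 2641 (without replicate 2) to 5780 for muscle, 134 (without replicate 1) to 7425 (without replicate 3) for neurons A, 5521 (without replicate 2) to 8658 for neurons B and 3840 (without replicate 1) to 5270 for soma. They were 0 (without replicate 1 or 2) to 976 (without IP replicate 3) for neurons A against B, 3137 (without replicate 3) to 5107 and 582 (without replicate 2) to 2755 for the ubiquitous IP against polysomes and pooled fractions, 0 (without replicate 2) to 437 for polysomes against pooled fractions and 0 to 1 (without replicate 1) for wild-type polysomes. Where limma called 0, genes at an unadjusted p under 0.05 numbered 2848 (neurons A), 837 and 962 (neurons A against B without replicates 1 and 2), 2340 (polysomes against pooled fractions), and 270 and 1003 (wild-type polysomes without replicates 2 and 3).

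Among named genes and differences, 91, 75 and 45 lost their call without replicates 1, 2 and 3, 11 lost and 11 gained it with the block, and 8 lost and 17 gained it with equal-sum scaling. Of list tests, 280 lost their call with an estimated correlation, 82 lost and 31 gained it with fry, and none changed direction past the threshold.

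DESeq2 and its size factors, which need whole counts, and a joint fit of all 54 libraries were not run. Sums over transcripts, and settings planned for tables of statistics alone (baseMean of at least 100, an absolute log2 of at least 1, FDR 0.01), were not run on the counts of genes, as the tables hold genes and values per library. Depth limits ratios of genes near the minimum mean of 10, since in the shallowest library, intestine IP replicate 2, 1 read stood for 7.14 normalized counts. Neurons A IP replicate 3 had 7896 genes at 0. Simulated 4-fold recovery, with 200 genes changed, was low in both experiments.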

Other observations

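Comparing GLD-1 targets with other germline mRNAs and counting genes shared by 5 IPs were chosen only after the lists had been tested. Of 12030 genes tested in all 5 promoter-driven IPs, 92 rose in all 5, where independent lists would give 5.81, and 210 fell in all 5 (3.72). Among those that rose, the largest lowest log2 was 3.12, for Y105C5A.17. The carbonic anhydrase gene cah-4 rose by log2 7.84 in intestine, 6.71 in neurons A, 5.70 in neurons B, 4.28 in muscle and 1.94 in soma, and stood at 0.32 in the ubiquitous IP.

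Across genes, coding length had a Spearman correlation with log2 of -0.386 in ubiquitous polysomes, -0.293 in wild-type polysomes, -0.259 in the soma IP and -0.249 in the pooled fractions, and -0.00832 in the ubiquitous IP.

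The 17 GLD-1 targets lay below the 38 other germline list genes by a median log2 of -0.82 in ubiquitous (adjusted p = 0.0361 by 100000 permutations) and -0.46 in wild-type polysomes (adjusted p = 0.0381). Genes were shuffled as if independent, without adjusting for coding length. With an estimated correlation the GLD-1 list passed in neither, and repression beyond other germline mRNAs stays open. The pooled fractions (-0.27, adjusted p = 0.14) and ubiquitous IP (-0.32, adjusted p = 0.255) did not pass. The size was not compared between fractions.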
